A study of Eublepharis macularius with 8 samples.

How the data were processed

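RNA was sequenced from whole functional and developing teeth of adult leopard geckos, as 4 libraries of each. Per the labels' protocols, libraries were made with a stranded mRNA kit and read as paired ends of 59 bases. Replicates 1 to 3 came from females (3 teeth per sample) and replicate 4 from males (10 functional or 11 developing teeth).

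The deposited values are estimated counts per gene, 1 column per library, not normalized. Per the submitters' processing notes they were made with kallisto, which assigns reads to transcripts without a genome alignment. The version of kallisto, its strand setting, the genome build, the annotation and any filter are not given in the sources used here. Of the values, 34.2% were not whole, and all were rounded to whole numbers. Kallisto divides reads between near-identical transcripts, so the values of close paralogs are uncertain. Row names were matched to the gene symbols of a RefSeq table of assembly MPM_Emac_v1.0, used for names only. Of 22488 names, 22407 matched, and the 81 that did not (between 0.909% and 1.406% of each library's counts) were left out of library sizes and tests. No coordinates are given, since the build behind the counts is not known.

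Libraries held between 14144573 and 30935120 counts. Libraries of a group correlated between 0.858 and 0.969, and libraries of different groups between 0.83 and 0.955. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3) at its defaults, which left 15491 genes, 11863 with a symbol and 3628 with a placeholder identifier. TMM normalization gave factors between 0.752 and 0.853 in functional and between 1.104 and 1.386 in developing libraries. Functional was compared with developing by edgeR's quasi-likelihood test without a covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05, and log2 fold changes are functional minus developing. Standard errors are the log2 fold change divided by the square root of the test's F statistic. CPM are given as mean ± SD over 4 libraries on TMM-scaled library sizes. A term for male minus female libraries, called the collection term here though the labels give no date of collection (the male libraries were deposited under record numbers apart from the other 6), was tested in a model with tissue, and the interaction in a model with both and their product, where the spread comes from the female libraries.

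Fixed before the data were examined were 24 gene lists: odontoclast and osteoclast resorption, V-ATPase subunits, osteoclast differentiation signals, monocytes and macrophages, granulocytes and mast cells, lymphocytes, enamel, dentin, dental epithelium, dental mesenchyme, cell cycle, matrix proteases and inhibitors, inflammatory mediators, semaphorins with their receptors, nuclear oxidative phosphorylation, endothelium, pericytes and smooth muscle, red cells, Schwann cells, skeletal muscle, oral mucosa, osteocytes and cementum or bone, immediate early and stress genes, and Wnt antagonists and targets. The tests, most alternatives and the rule for named genes were fixed at the same time. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Fry asks whether a list's members change at all, not whether they change against the other genes. A list score is the mean log2 CPM (prior count 2) of its tested members relative to the 8 libraries. Adjusted p-values over a list alone use only that list's tested members.

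Named genes were the 12 largest rises and 12 largest falls past the threshold with a symbol, a mean of at least 10 CPM in the higher group and no overlap between groups. Added were the 4 members of each list with the smallest p, a fixed set of odontoclast, enamel, dentin, signaling and proliferation genes, and the 5 genes with the smallest p for the collection term and for the interaction. For genes with any library at 0 or at 1 to 3 counts, CPM are given without a fold change. Some genes that this rule names are not reported here.

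The libraries share replicate numbers across groups. Deviations from the group mean correlated between same-numbered libraries at 0.16 to 0.68, over 0.1 in all 4 pairs, so by a rule set in advance the numbers were taken as pairs. Differently numbered libraries reached 0.41 (functional replicate 3 with developing replicate 1). In the other group, 4 of the 8 libraries correlated best with the library of their own number, so the pairing is uncertain. The main fit, also set in advance, ignores the pairing. The fit with the replicate number as a block is given as an alternative.

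The scripts were tested on simulated counts drawn from the real means and library sizes. For functional against developing teeth over 15300 genes, 8 of 50 genes changed 2-fold were recovered, 40 of 50 changed 4-fold, 40 of 50 changed 8-fold and 48 of 50 changed 16-fold, and 7 unchanged genes were called. In a separate simulated draw, with the female libraries alone, 1, 25, 36 and 43 of 50 were recovered at these sizes. For the lists, 3 of 3 raised 2-fold and 0 of 21 unchanged lists were called. The genes were simulated independently of each other, while the estimated correlation within a real list reached 0.863 (cell cycle). The simulation therefore does not show how often camera with the preset correlation calls unchanged lists in the real data. Divisions of the 8 real libraries into 4 and 4 that mixed the groups put between 1 and 15 lists past the threshold.

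Alternatives were RLE normalization, DESeq2 1.42.0, no filter, a stricter filter (CPM of 1 in 4 libraries), a 2-fold minimum, unrounded counts, the replicate block, the collection covariate, females only and each library left out. Added after the data were seen were the collection covariate without functional replicate 1, limma-voom with quality weights, the collection covariate in the list test, each library left out for the collection term and the interaction, and an exact permutation test of list scores. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).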

Results

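RNA was measured in whole teeth of adult leopard geckos (Eublepharis macularius), a lizard that replaces its teeth throughout life. The series title names odontoclasts, the multinucleate cells that resorb tooth tissue, and the design compares functional teeth, those in use, with developing teeth, which form to replace them. There were 8 libraries, 4 of functional teeth and 4 of developing teeth. Replicates 1 to 3 of each group came from females with 3 teeth per sample, and replicate 4 came from males with 10 functional or 11 developing teeth. The labels name the 4 libraries of a group biological replicates without saying that each came from other animals, so the p-values measure the spread between these samples. RNA integrity numbers lay between 8.8 and 9.6. The functional libraries held 21020159, 30665133, 22923362 and 30935120 estimated counts, and the developing libraries 21739182, 19919888, 14144573 and 20393818, in replicate order. The type I collagen genes COL1A1 and COL1A2 together took 31.8% ± 1.96 (SD, n = 4) of all counts in functional teeth and 12.2% ± 8.37 in developing teeth. That share was 20.4%, 18.4%, 5.65% and 4.31% in developing replicates 1 to 4.

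The comparison of functional with developing teeth asked which transcripts differ between teeth in use and teeth being formed. The hedgehog pathway genes PTCH1 and GLI1, the ameloblast gene SP6 and mitotic genes such as KIF20A and FOXM1 were lower in functional teeth, and the bone matrix genes BGLAP and OMD and the macrophage genes VSIG4, CTSS and ITGB2 were higher. Of 15491 genes tested, 124 were higher and 312 lower in functional teeth (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 276 of the lower and 91 of the higher genes differed at least 2-fold. In 2326 genes, 15% of those tested, the functional and developing libraries did not overlap, where 2.86% is the average expected by chance. Genes vary together, so the share in any 1 division of the libraries can differ from that average. The share was not computed for other divisions. DESeq2's Wald test called 721 genes higher and 959 lower, so that 42.9% of its calls were higher against 28.4% in edgeR. With the replicate number as a block, 69 genes were higher and 151 lower, and 163 of the 436 genes were called in both fits. With a covariate for male and female libraries, 246 genes were higher and 425 lower. Among the 6 female libraries alone 1 gene was higher (LOC129337569) and 2 were lower (HS3ST3B1 and CACNA2D3, named after their values were seen), with 1079 higher and 1396 lower at an unadjusted p under 0.05, and the male pair has no replicate. The counts of higher and lower genes were 45 and 123 without functional replicate 1, 7 and 9 without functional replicate 2, 7 and 5 without functional replicate 3, and 2 and 6 without functional replicate 4. They were 7 and 22 without developing replicate 3, and 12 and 41 without developing replicate 4. Of the 48 named genes past the threshold, 48 lost the call without functional replicate 4 and 46 without functional replicate 2 or 3.

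**Figure D1:**
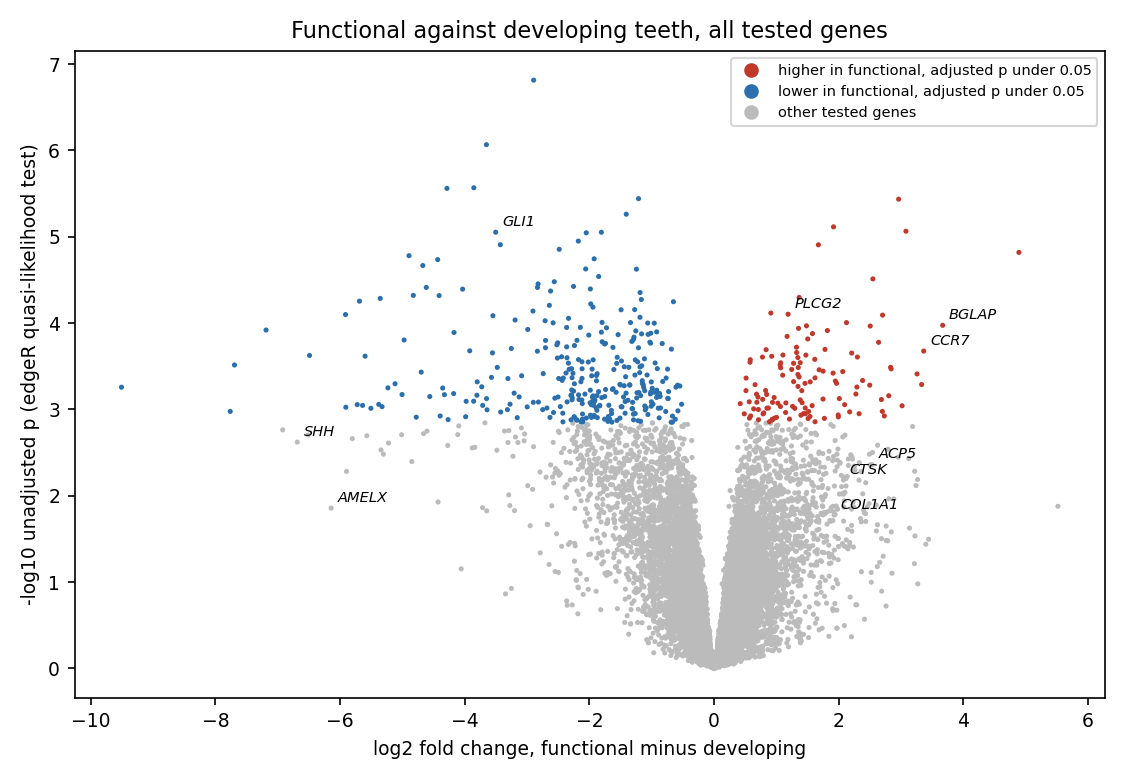
Each point is a tested gene, with the log2 fold change of functional over developing teeth on the x axis and the -log10 of the unadjusted p on the y axis. Red points are the 124 genes higher and blue points the 312 genes lower in functional teeth at an adjusted p under 0.05; SHH, AMELX, ACP5, CTSK and COL1A1 lie below that threshold.

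Among 20 tested members of the enamel list, 1 passed the test over all genes and 12 were lower and 1 higher when adjusted over the list alone. The gene that passed, SP6, encodes a transcription factor of ameloblasts, the enamel-forming cells. It fell from 162 ± 67 CPM (counts scaled to library size; mean ± SD, n = 4) in developing teeth to 22.8 ± 7.95 in functional teeth, a log2 fold change of -2.82 ± 0.35 (SE) with an adjusted p of 0.0196. The enamel matrix genes had larger differences that did not pass. AMELX, the gene of the main enamel matrix protein amelogenin, averaged 8504 ± 6657 CPM in developing and 120.3 ± 233 CPM in functional teeth (log2 fold change -6.14 ± 1.98, or -11.15 without functional replicate 1, adjusted p = 0.129). Functional replicate 1 held 470.0 CPM of AMELX while functional replicates 2, 3 and 4 held 3.69, 3.56 and 3.91. AMBN (log2 fold change -5.34 ± 1.29, adjusted p = 0.0664), ENAM (-6.51 ± 1.47, adjusted p = 0.0569) and AMTN (-4.61 ± 1.02, adjusted p = 0.055), which also encode enamel matrix proteins, were lower in all 4 functional libraries than in any developing library. So were MMP20, the protease that processes enamel matrix (-3.29 ± 0.73, adjusted p = 0.055), and the laminin gene LAMA3 (208 ± 117 CPM in developing and 51.8 ± 11.3 CPM in functional teeth, adjusted p = 0.055). The list as a whole passed camera with a preset correlation (adjusted p = 5.70e-05), and its adjusted p was 0.318 with an estimated correlation.

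Of 29 tested genes of the dental mesenchyme list 4 fell and 0 rose in functional teeth, 8 had a positive log2 fold change, and 11 were lower when adjusted over the list alone. PTCH1, the hedgehog receptor and itself a transcriptional target of the pathway, fell from 318 ± 199 to 19.4 ± 4.56 CPM (log2 fold change -4.03 ± 0.52, adjusted p = 0.0196). GLI1, a transcription factor induced by the same pathway, fell by 3.50 ± 0.37 on the log2 scale (adjusted p = 0.0116). LHX8, a homeobox gene of tooth mesenchyme, fell by 1.74 ± 0.27 (adjusted p = 0.0276). FGF3, a growth factor gene of the tooth germ, had 3.11 ± 3.27 CPM in developing and 0.0655 ± 0.0688 CPM in functional teeth, with no count in functional replicate 3 (adjusted p = 0.0424, and 0.073 with the replicate block). The list passed camera with the preset correlation (adjusted p = 4.32e-06), its adjusted p was 0.0898 with an estimated correlation, and it passed limma's fry test (adjusted p = 0.00175). No other list passed fry. The fry adjusted p was 0.0735 for each of the enamel, cell cycle, macrophage and endothelium lists and 0.0875 for the resorption list. In the dental epithelium list, 1 of 22 tested genes fell, 5 were lower when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.115). It passed without functional replicate 1 (0.0379) or developing replicate 1 (0.0133). The gene was FGF9, another growth factor of the tooth germ (log2 fold change -2.64 ± 0.36, adjusted p = 0.0224). SHH, the hedgehog ligand made by tooth epithelium, averaged 389.6 ± 199 CPM in developing and 3.81 ± 6.83 CPM in functional teeth without passing (adjusted p = 0.0612), with 14.1 CPM in functional replicate 1 and at most 0.568 CPM in functional replicates 2 to 4. EDAR, a receptor of ectodermal organ development, had a log2 fold change of -2.18 ± 0.58 (adjusted p = 0.0822, and 0.0462 with the replicate block), and FOXI3 one of -2.01 ± 0.53 (adjusted p = 0.082).

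**Figure D2:**
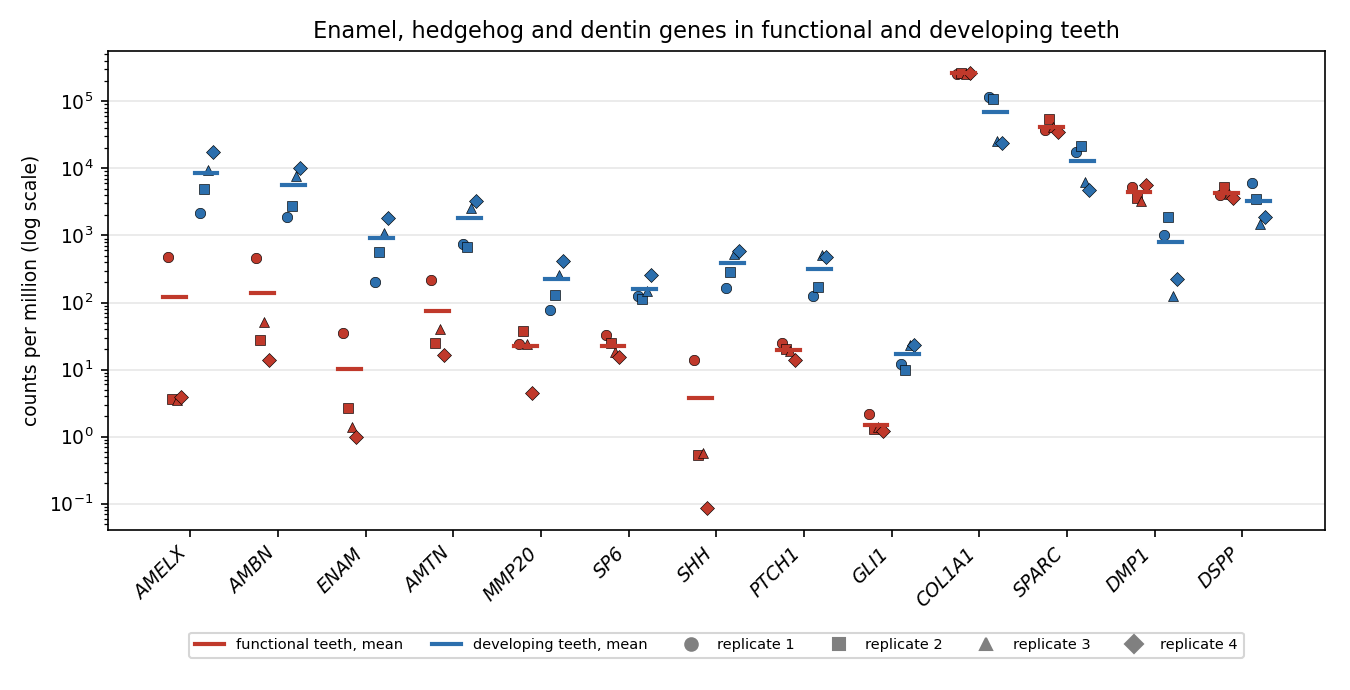
CPM on a log axis for enamel, hedgehog and dentin genes, with 1 symbol per library (circle, square, triangle and diamond for replicates 1 to 4) and a bar at each group's mean. AMELX stands at 470.0 CPM in functional replicate 1 and between 3.56 and 3.91 CPM in the other functional libraries, and COL1A1 is lower in developing replicates 3 and 4 than in developing replicates 1 and 2.

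Every one of the 31 tested cell cycle genes had a negative log2 fold change, with a median of -1.85; 11 fell over all genes and 29 were lower when adjusted over the list alone. KIF20A, a mitotic kinesin, fell from 10.7 ± 5.23 to 1.64 ± 0.462 CPM (log2 fold change -2.70 ± 0.42, adjusted p = 0.0276). FOXM1, a transcription factor of the mitotic program, fell by 2.36 ± 0.39 (adjusted p = 0.031), the mitotic kinase gene PLK1 fell by 1.56 ± 0.26 (adjusted p = 0.0315), and the centromere motor gene CENPE fell by 2.12 ± 0.38 (adjusted p = 0.0354, and 0.0555 with the replicate block). MKI67, the common proliferation marker, averaged 43.8 ± 27 CPM in developing and 12.9 ± 4.94 CPM in functional teeth and did not pass (adjusted p = 0.0912). The block left 4 genes of the list called. The list passed camera with the preset correlation (adjusted p = 1.48e-21), and its adjusted p was 0.318 with an estimated correlation. In the list of Wnt antagonists and targets, 3 of 21 genes fell, and 8 were lower and 3 higher when adjusted over the list alone. RSPO4, which encodes an enhancer of Wnt signaling, averaged 12.4 ± 11.2 CPM in developing and 0.525 ± 0.158 CPM in functional teeth (log2 fold change -4.56 ± 0.88, adjusted p = 0.0403, and 0.0555 with the replicate block). SOST, the gene of the Wnt antagonist sclerostin, fell by 3.71 ± 0.74 (adjusted p = 0.0426, and 0.093 with the block), and the Wnt inhibitor gene APCDD1 fell by 0.83 ± 0.13 (adjusted p = 0.0276). NKD1 did not pass (-0.69 ± 0.15, adjusted p = 0.0549). This list passed camera at an adjusted p of 0.0498 with the preset correlation, and had an adjusted p of 0.318 with an estimated correlation. Its adjusted p was 0.111, 0.0691, 0.0653 and 0.0662 without functional replicates 1, 2 and 4 and developing replicate 4, in that order.

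Among genes with a symbol and at least 10 CPM in developing teeth, the largest falls included SLC26A1, SLC39A8, SP5, ASCL4, TESC, SLC6A15, CALB1, CPE, TLL1, RSPO4 and SMCO1. The anion transporter gene SLC26A1 averaged 21.4 ± 31 CPM in developing teeth and had no count in functional replicates 2 and 3 (adjusted p = 0.0382). CALB1, which encodes the calcium-binding protein calbindin, fell from 257 ± 189 to 9.08 ± 2.69 CPM (log2 fold change -4.83 ± 0.63, adjusted p = 0.0207). TLL1, a metalloprotease gene of the tolloid family, fell by 4.67 ± 0.55 (adjusted p = 0.0159), and the amino acid transporter gene SLC6A15 fell from 10.7 ± 6.39 to 0.266 ± 0.242 CPM (adjusted p = 0.0211). ASCL4 averaged 10.7 ± 7.44 CPM in developing and 0.217 ± 0.229 CPM in functional teeth (adjusted p = 0.031). The falls of the zinc transporter gene SLC39A8 (-5.91 ± 1.19), SP5 (from 12.8 ± 11.4 to 0.256 ± 0.198 CPM), TESC (-5.51 ± 1.11), the carboxypeptidase gene CPE (-4.70 ± 0.82) and SMCO1 (-4.33 ± 0.83) had adjusted p-values of 0.043, 0.0426, 0.043, 0.0343 and 0.0403 in that order, and of 0.114, 0.0895, 0.0724, 0.0739 and 0.0685 with the replicate block.

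Of the mineralized matrix genes, BGLAP and OMD rose and ALPL fell in functional teeth. In the odontoblast and dentin list, 22 of 25 tested genes had a positive log2 fold change, 1 rose and 1 fell over all genes, and 10 were higher and 2 lower when adjusted over the list alone. BGLAP, which encodes the bone and dentin protein osteocalcin, rose from 0.709 ± 0.259 to 9.15 ± 6.02 CPM (log2 fold change 3.67 ± 0.54, adjusted p = 0.0257). ALPL, the alkaline phosphatase of mineralization, fell from 169 ± 86.5 to 29.8 ± 7.88 CPM (adjusted p = 0.0276). COL1A1 took 21.1% ± 0.978 of counts in functional and 7.85% ± 5.31 in developing teeth and did not pass (log2 fold change 1.93 ± 0.65, adjusted p = 0.139). Its share was 13.1%, 11.8%, 3.55% and 3.01% in developing replicates 1 to 4. The dentin matrix gene DMP1 (2.46 ± 0.79, adjusted p = 0.127), the secreted kinase gene FAM20C (0.92 ± 0.22, adjusted p = 0.0666) and SPARC (1.72 ± 0.52, adjusted p = 0.113) did not pass, with every functional library above every developing library. DSPP, the gene of the main non-collagenous dentin protein, averaged 4261 ± 728 CPM in functional and 3227 ± 2042 CPM in developing teeth (adjusted p = 0.611). The list passed camera with the preset correlation (adjusted p = 8.43e-07), and had an adjusted p of 0.382 with an estimated correlation.

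The bone and cementum list, which shares BGLAP with the dentin list, had 2 rises and 1 fall among 13 tested genes, and 6 genes higher and 2 lower when adjusted over the list alone. OMD, the gene of the small matrix proteoglycan osteomodulin, rose from 3.81 ± 1.3 to 27.2 ± 17.8 CPM (log2 fold change 2.83 ± 0.49, adjusted p = 0.0328). WIF1, a secreted Wnt inhibitor gene, did not pass (-0.83 ± 0.20, adjusted p = 0.0634). The list passed camera with the preset correlation (adjusted p = 0.0126) and had an adjusted p of 0.336 with an estimated correlation. Among matrix proteases and their inhibitors, 1 of 23 genes rose, and 6 were higher and 1 lower when adjusted over the list alone. ADAMTS14, a procollagen processing protease, rose from 4.5 ± 2 to 19.7 ± 1.37 CPM (log2 fold change 2.13 ± 0.31, adjusted p = 0.0251). The lysosomal protease gene CTSB (0.68 ± 0.15, adjusted p = 0.0505), the gelatinase gene MMP2 (1.04 ± 0.24, adjusted p = 0.0582) and MMP19 (-0.89 ± 0.23, adjusted p = 0.0763) did not pass. The adjusted p of this list in camera was 0.0126 with the preset correlation and 0.419 with an estimated correlation.

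The resorption genes of odontoclasts and osteoclasts averaged more in functional teeth, with 0 of 24 tested genes past edgeR's test over all genes and 7 higher when adjusted over the list alone. At an unadjusted p under 0.05 there were 10 higher and 1 lower, and DESeq2 called 7 higher and 0 lower. Their median log2 fold change was 0.56, and 20 of the 24 were positive. ACP5, the tartrate-resistant acid phosphatase used to stain odontoclasts, averaged 176 ± 166 CPM in functional and 30.3 ± 17.1 CPM in developing teeth (log2 fold change 2.54 ± 0.66, or 1.63 without functional replicate 4, adjusted p = 0.0786). CTSK, the collagen-degrading protease of resorbing cells, averaged 339 ± 314 against 80.2 ± 26 CPM (2.08 ± 0.58, or 1.19 without functional replicate 4, adjusted p = 0.0921), and MMP9 averaged 270.3 ± 179 against 61.4 ± 39 CPM (2.14 ± 0.58, adjusted p = 0.089). Among the female libraries alone the log2 fold changes were 1.07 for CTSK and 1.41 for MMP9, and the mean of the list was 0.819 with all libraries and 0.493 without functional replicate 4. All 4 functional libraries lay above all 4 developing libraries for these 3 genes. Functional replicate 4, the male library, was the highest for each, with 423 CPM of ACP5, 807 of CTSK and 523 of MMP9. The score of the whole list did overlap between groups, at -0.03 in functional replicate 1 and -0.02 in developing replicate 1. Functional minus developing, the list differed by -0.01, 0.67, 0.71 and 1.63 (log2) in replicate numbers 1 to 4, so number 1 showed no rise. CALCR, the calcitonin receptor gene (1.07 ± 0.251 CPM in functional and 0.255 ± 0.212 CPM in developing teeth, adjusted p = 0.077), the proton pump gene TCIRG1 (0.91 ± 0.25, or 0.59 without functional replicate 4, adjusted p = 0.0914) and NFATC1, the main transcription factor of osteoclast formation (1.09 ± 0.38, adjusted p = 0.149), did not pass. Nor did the cell fusion genes DCSTAMP (0.82 ± 0.31, or 0.53 without functional replicate 4, adjusted p = 0.175) and OCSTAMP (0.53 ± 0.54, or -0.29 without functional replicate 4, adjusted p = 0.603). The list passed camera with the preset correlation (adjusted p = 5.70e-05), and its adjusted p was 0.35 with an estimated correlation. The macrophage list score was 0.46 ± 0.49 (SD, n = 4) in functional and -0.46 ± 0.30 in developing teeth.

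The signals that govern odontoclast formation showed 1 call. In the differentiation list, 1 of 24 genes rose, 2 were higher and 1 lower when adjusted over the list alone, and the list did not pass camera (direction up, adjusted p = 0.266), with a median log2 fold change of -0.04 and a mean of 0.337, or 0.15 without functional replicate 4. PLCG2, a phospholipase of myeloid receptor signaling, rose from 8.42 ± 1.56 to 19.2 ± 2.29 CPM (log2 fold change 1.19 ± 0.17, adjusted p = 0.0244). TNFSF11, the gene of the osteoclast-inducing ligand RANKL, averaged 60.1 ± 17.5 CPM in functional and 64.8 ± 35.3 CPM in developing teeth, and the difference was smaller than its standard error (-0.11 ± 0.40, adjusted p = 0.892). TNFRSF11B, the gene of the RANKL decoy receptor osteoprotegerin, had 23.8, 0.406, 1.14 and 164 CPM in functional replicates 1 to 4 and at most 1.61 CPM in developing libraries (adjusted p = 0.127). The RANKL receptor gene TNFRSF11A (0.88 ± 0.50, or 0.31 without functional replicate 4, adjusted p = 0.342), the macrophage growth factor gene CSF1 (1.25 ± 0.41, adjusted p = 0.134) and the myeloid transcription factor gene SPI1 (1.58 ± 0.40, adjusted p = 0.0747) did not pass. The list of V-ATPase subunits, parts of the proton pump that acidifies lysosomes and resorption pits, had 0 of 14 genes past edgeR's test over all genes (5 higher at an unadjusted p under 0.05 and 2 in DESeq2), 1 higher when adjusted over the list alone and 13 with a positive log2 fold change. Its adjusted p in camera was 0.00543 with the preset correlation and 0.419 with an estimated correlation. Its mean of 0.359 was 0.233 without functional replicate 4. Its leading members were ATP6V0E1 (0.66 ± 0.16, adjusted p = 0.0664), ATP6V1G1 (0.57 ± 0.19, adjusted p = 0.136), ATP6V0D1 (0.39 ± 0.15, adjusted p = 0.189) and ATP6AP1 (0.69 ± 0.29, or 0.34 without functional replicate 4, adjusted p = 0.213).

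**Figure D3:**
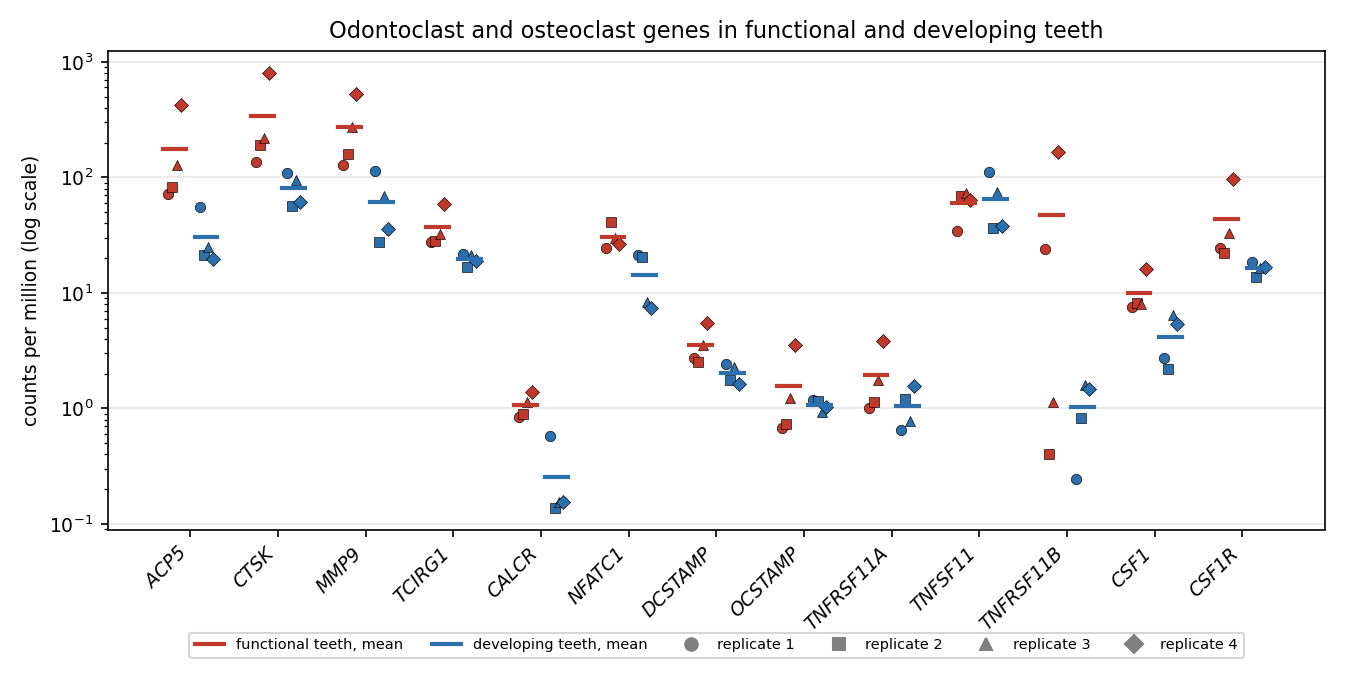
CPM on a log axis for odontoclast and osteoclast genes, with 1 symbol per library (circle, square, triangle and diamond for replicates 1 to 4) and a bar at each group's mean. Functional replicate 4 is the highest library for ACP5 at 423 CPM and for CTSK at 807 CPM, and the groups overlap for TNFSF11 and TNFRSF11B.

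Of 17 tested genes of the macrophage list, 14 had a positive log2 fold change, 3 rose and 0 fell in functional teeth, and 8 were higher when adjusted over the list alone. VSIG4, a complement receptor of tissue macrophages, rose from 1.55 ± 0.852 to 11.2 ± 4.15 CPM (log2 fold change 2.84 ± 0.49, adjusted p = 0.0328). The leukocyte integrin gene ITGB2 rose by 1.35 ± 0.22 on the log2 scale (adjusted p = 0.031), and CTSS, a lysosomal protease of antigen-presenting cells, by 2.38 ± 0.43 (adjusted p = 0.0367, and 0.0518 with the replicate block). The complement gene C1QA (1.98 ± 0.52, adjusted p = 0.0804) and CSF1R, the CSF1 receptor of the macrophage lineage (1.42 ± 0.46, or 0.70 without functional replicate 4, adjusted p = 0.13), did not pass. The list passed camera with the preset correlation (adjusted p = 1.08e-05) and had an adjusted p of 0.318 with an estimated correlation. The lists of lymphocytes (adjusted p = 0.116) and of granulocytes and mast cells (adjusted p = 0.323) did not pass camera. Lymphocytes passed without functional replicate 4 (adjusted p = 0.0368) or developing replicate 1 (0.0139). Of 10 tested lymphocyte genes 1 fell and 1 was lower when adjusted over the list alone: TCF7, a transcription factor of T cells and also of Wnt signaling (-0.87 ± 0.17, adjusted p = 0.0403, and 0.0591 with the replicate block). The genes CD247 (-1.79 ± 0.78, or -0.67 without developing replicate 4) and BLNK (-0.55 ± 0.24) did not pass. Among 6 tested granulocyte and mast cell genes 0 passed edgeR's test over all genes and 0 when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 and 0 in DESeq2. CSF3R (0.97 ± 0.38), KIT (-1.53 ± 0.62), HDC (1.34 ± 0.68, or 0.72 without functional replicate 4) and GATA2 (0.90 ± 0.65, or 0.56 without developing replicate 2 and 1.35 without developing replicate 4) led by unadjusted p.

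Vessel, muscle, respiration and early response lists averaged more in functional teeth, and edgeR's test over all genes called 0 members in each. At an unadjusted p under 0.05 there were 15 endothelial, 2 respiration, 1 pericyte and 1 early response genes higher, and 4 muscle genes higher and 1 lower. DESeq2 called 9 endothelial genes higher, 1 muscle gene higher and 1 lower, and 0 in the other lists of this group. When adjusted over the list alone, 0 genes passed in the respiration, pericyte, muscle and early response lists. Of 25 endothelial genes, 24 had a positive log2 fold change and 9 were higher when adjusted over the list alone; the fenestration gene PLVAP averaged 185 ± 62.1 CPM in functional and 59.1 ± 26.7 CPM in developing teeth (adjusted p = 0.0568). The genes MMRN1 (1.27 ± 0.29), ESAM (1.24 ± 0.32) and the tight junction gene CLDN5 (1.26 ± 0.33) followed by unadjusted p. The endothelial list had an adjusted p in camera of 2.11e-10 with the preset correlation and 0.318 with an estimated correlation. All 30 nuclear genes of oxidative phosphorylation had positive log2 fold changes, with a median of 0.27 and ATP5PO (0.73 ± 0.30), SDHB (0.62 ± 0.27, or 0.39 without functional replicate 4), NDUFA6 (0.41 ± 0.18) and NDUFB9 (0.39 ± 0.18) leading. That list had an adjusted p of 0.00431 with the preset and 0.516 with an estimated correlation. Pericyte and smooth muscle genes had an adjusted p of 0.0239 with the preset and 0.405 with an estimated correlation, and 0.0589, 0.0721 and 0.0944 without functional replicate 3 and developing replicates 2 and 4. They were led by PDGFRB (0.83 ± 0.33), LMOD1 (1.73 ± 0.79, or 1.02 without functional replicate 2), ABCC9 (0.84 ± 0.43, or 0.48 without functional replicate 3) and KCNJ8 (1.20 ± 0.66, or 0.62 without functional replicate 3 and 2.09 without developing replicate 1). Skeletal muscle genes had an adjusted p of 0.0271 and 0.318 in the same order, and 0.0552, 0.0589 and 0.0573 without functional replicates 2 and 3 and developing replicate 4. ACTN3 (2.36 ± 0.82, or 3.59 without developing replicate 2) and XIRP2 (1.76 ± 0.70) had positive and the alpha-actin gene ACTA1 (-3.71 ± 1.20, or -1.42 without developing replicate 3) a negative log2 fold change. ACTN2 averaged 1.04 ± 0.419 CPM in functional and 0.247 ± 0.263 CPM in developing teeth. Immediate early and stress genes had adjusted p-values of 0.00482 and 0.472. Without functional replicate 1 the list's adjusted p was 0.0549 (mean 0.35 against 0.624), and without developing replicate 4 it was 0.0944 (mean 0.414). The list was led by ATF3 (1.81 ± 0.69, or 1.19 without functional replicate 2), NR4A1 (1.65 ± 0.75, or 0.91 without functional replicate 1), DDIT3 (0.73 ± 0.34) and IER3 (1.27 ± 0.62, or 0.28 without functional replicate 1).

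**Figure D4:**
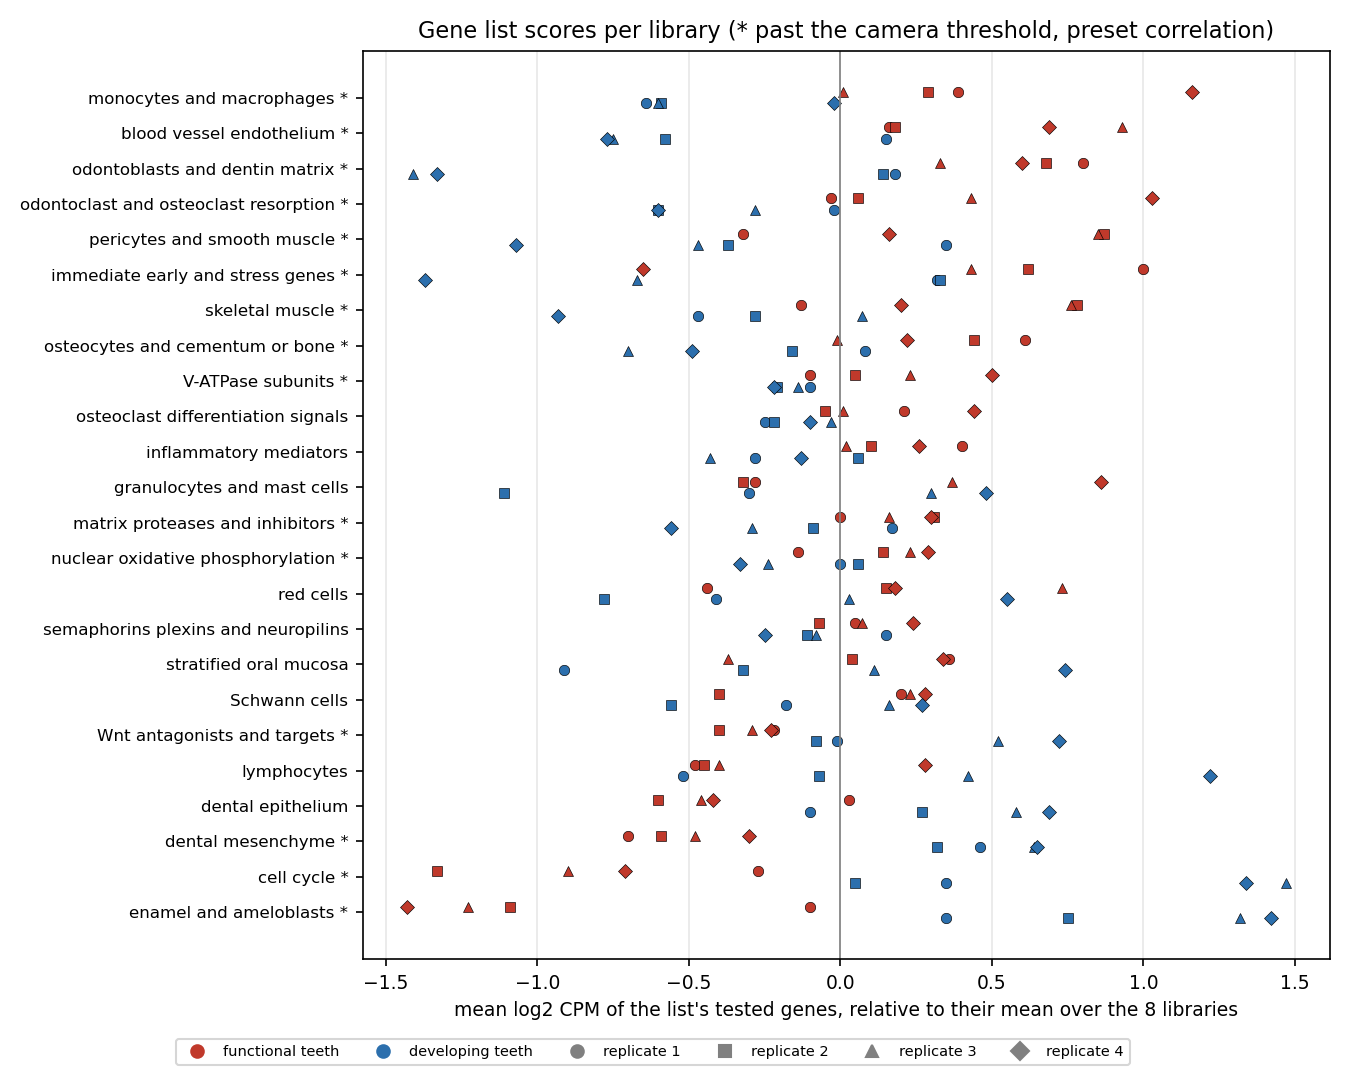
Each row is a gene list and each symbol a library (red functional, blue developing; circle, square, triangle and diamond for replicates 1 to 4), placed at the list's mean log2 CPM relative to its mean over the 8 libraries. For the cell cycle list the functional libraries sit between -1.33 and -0.27 and the developing libraries between 0.05 and 1.47; for the resorption list functional replicate 4 sits at 1.03.

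In the inflammatory mediator list, which did not pass camera (adjusted p = 0.269), 1 of 11 genes rose and 1 fell, and 1 was higher and 1 lower when adjusted over the list alone. TGFB1, the growth factor stored in bone and dentin matrix, rose from 158 ± 66.4 to 428 ± 57.3 CPM (log2 fold change 1.44 ± 0.30, adjusted p = 0.046, and 0.0521 with the replicate block). TNFAIP3, an inhibitor of NF-kappaB signaling, fell by 1.19 ± 0.17 (adjusted p = 0.025). PTGS2 (1.37 ± 0.49) and NFKBIA (0.65 ± 0.33, or 0.37 without functional replicate 1) did not pass. Semaphorin genes went both ways, with 1 rise and 2 falls among 27 genes and 4 higher and 4 lower when adjusted over the list alone. SEMA3E, a secreted guidance factor, rose from 78.6 ± 32 to 207 ± 27.9 CPM (1.40 ± 0.29, adjusted p = 0.0469). SEMA6A fell by 1.11 ± 0.22 (adjusted p = 0.0427) and SEMA3F fell by 1.29 ± 0.27 (adjusted p = 0.0486, and 0.0763 with the replicate block), while SEMA5A did not pass (284 ± 27.6 CPM in functional and 142 ± 42.2 CPM in developing teeth, adjusted p = 0.0544). The semaphorin list did not pass camera (adjusted p = 0.354). The marker lists of stratified oral mucosa (adjusted p = 0.269), red cells (adjusted p = 0.296) and Schwann cells (adjusted p = 0.526) did not pass camera with all libraries. That of skeletal muscle did (adjusted p = 0.0271 with the preset correlation). Oral mucosa passed among the female libraries alone (direction up, adjusted p = 0.0281) and without developing replicate 4 (adjusted p = 0.0176), and so did red cells (adjusted p = 0.0467 and 0.04996). In the mucosa list 1 of 12 genes fell and 1 was lower when adjusted over the list alone. This gene, ABCA12, a lipid transporter gene of cornified epithelium, fell by 3.16 ± 0.66 (adjusted p = 0.0478, and 0.0663 with the block). The desmosome genes EVPL (68.5 ± 26.2 CPM in functional and 34.2 ± 17.8 CPM in developing teeth), PERP (log2 fold change -0.46 ± 0.24) and PKP3 (0.60 ± 0.35, or 0.40 without developing replicate 1 and 0.93 without developing replicate 4) did not pass. In the Schwann cell list 1 of 8 genes rose, GFRA3, and 1 was higher when adjusted over the list alone. In the red cell list 0 of 8 genes passed edgeR's test over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or in DESeq2. The red cell genes RHAG (0.70 ± 0.43), EPOR (0.61 ± 0.46), HEMGN (0.22 ± 0.47) and KLF1 (0.29 ± 0.62) and the Schwann cell genes NGFR (-1.81 ± 0.63, or -1 without developing replicate 1, which held 66.8 CPM), L1CAM (-1.24 ± 0.65) and PRX (0.27 ± 0.15) did not pass. The values of these 4 red cell genes moved by over 1.5 times without at least 1 library.

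Among genes with a symbol and at least 10 CPM in functional teeth, the largest rises lay in CCR7, BARX2, VSIG4, OMD, CMKLR2, NT5E, NRL, GPNMB, CTSS, GFRA3, ELF3 and CSTA. GPNMB, a glycoprotein gene of macrophages and osteoclasts, rose from 7.77 ± 2.85 to 44.3 ± 18.5 CPM (log2 fold change 2.51 ± 0.37, adjusted p = 0.0257). NT5E, the gene of the ectoenzyme CD73, rose from 6.49 ± 3.79 to 40.5 ± 8.53 CPM (adjusted p = 0.0276), and the transcription factor gene NRL by 2.55 ± 0.32 (adjusted p = 0.0191). The chemokine receptor gene CCR7 (3.37 ± 0.54), the homeobox gene BARX2 (3.02 ± 0.60), CMKLR2 (2.73 ± 0.57), the epithelial transcription factor gene ELF3 (2.29 ± 0.42), the neurotrophic receptor gene GFRA3 (2.33 ± 0.48) and the protease inhibitor gene CSTA (2.28 ± 0.43) had adjusted p-values of 0.0293, 0.0427, 0.0474, 0.0382, 0.046 and 0.0403. With the replicate block these were 0.0518, 0.0591, 0.0591, 0.078, 0.082 and 0.0531.

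The male libraries were compared with the female libraries over both tooth groups in 1 shared term, and not within each group, which holds 1 male library. The 2 male libraries share replicate number 4 and their deviations from the group mean correlated at 0.68, so the counts below rest on 1 male set that the model takes as 2 separate samples. In a model with tissue and this term, 563 genes were higher and 162 lower in the male libraries (edgeR's quasi-likelihood test, adjusted p under 0.05). The translation initiation factor gene EIF3G was higher in male libraries by 1.43 ± 0.12 (log2, SE; adjusted p = 0.00438), with 118 and 102 CPM in the male functional and developing libraries and at most 45 CPM in the 6 female libraries. APBB3 (3.01 ± 0.29), the phosphatase gene DUSP23 (1.83 ± 0.19) and PHTF2 (1.48 ± 0.16) were also higher and PRUNE2 lower (-3.44 ± 0.27), each with an adjusted p of 0.00438. Among lists, macrophages (camera with the preset correlation, adjusted p = 0.00105), lymphocytes (adjusted p = 0.0141) and oral mucosa (adjusted p = 0.0183) were higher in male libraries, and immediate early genes (adjusted p = 4.04e-09) and dentin genes (adjusted p = 0.0495) lower. The adjusted p-values of these 5 lists were 0.379, 0.597, 0.877, 0.379 and 0.877 with an estimated correlation. Sex, number of teeth and a separate deposit of the libraries change together with replicate number 4 and cannot be told apart. Without functional replicate 4 the counts were 1 and 3, without developing replicate 4 they were 246 and 20, and the count of lower genes was 74, 81, 107 and 101 without functional replicates 2 and 3 and developing replicates 1 and 2, in that order.

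The difference between functional and developing teeth was compared between the female pairs and the male pair. No gene passed edgeR's interaction test, with 278 genes at a positive and 237 at a negative interaction at an unadjusted p under 0.05, and DESeq2's Wald test called 20. The smallest unadjusted p-values with a symbol lay in IL22RA1 (interaction -3.62 on the log2 scale), TUBB3 (3.90), GALNT15 (2.77), CIART (-2.06) and SSTR2 (-2.53), each with an edgeR adjusted p of 0.937. ACP5 had a log2 fold change of 1.47 in females, and 423 and 19.6 CPM in the male functional and developing libraries. CTSK had 1.07 in females, and 807 and 61.1 CPM in the male libraries (adjusted p of each interaction = 0.937). The resorption list passed camera for the interaction with the preset correlation (adjusted p = 3.22e-09), and its adjusted p was 0.447 with an estimated correlation. The male pair is 1 functional and 1 developing library, so the smaller of these p-values reflects the spread over genes and not between males. On simulated counts for this test, 89 of 100 genes raised 64-fold in 1 library were recovered, and 0 genes changed 8-fold were recovered.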

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

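The tests of macrophages and depth in replicate 4, of the confounding of replicate 4, and of macrophages in developing replicates 1 and 2 were chosen after the results were seen. A library far from the other 3 of its group was found in 26 of 332 groups. Without 10 genes chosen for a difference of replicate 4 it was found in 18 of 312 (5.77%), where chance gives about 1 in 20.

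Of the 35 ways to divide the 8 libraries into 4 and 4, only the real one, which called 436 genes, called as many, and the highest other called 1. These 35 ways take the libraries as unpaired, so they exclude chance for the gene counts only if the replicate numbers are not pairs. Among the 8 divisions that part all 4 pairs the real one was the only 1 with as many and the highest other called 1, but 8 are too few for a share under 0.05; divisions that part fewer pairs called at most 0. For the lists, 2 of the 35 put as many past the threshold (15 in the real division, highest other 15), so chance cannot be excluded for the number of lists. The other division set functional replicates 1, 3 and 4 and developing replicate 1 against the rest, and among the divisions that part all 4 pairs the highest other was 14. Divisions with 2 functional and 2 developing libraries on each side put between 1 and 13 lists past the threshold. Passing camera with the preset correlation therefore does not by itself tie a list to the tissue.

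AMELX stood at 470 CPM in functional replicate 1 against at most 3.91 CPM in the other 3 functional libraries. If developing-tooth tissue was mixed into functional replicate 1, other genes of developing teeth should be raised too, and 18 such genes stood there at a median excess of 5.1% of their developing mean (quartiles 0.309 and 9.29; 16 positive). With replicates 2, 3 and 4 in its place, and other genes, each set being 20-fold lower in the remaining 3 libraries, the values were -0.113% (6 genes), 0.0472% (6) and 0.878% (9), so those sets are small and leave out genes raised in replicate 1. A share of developing tissue in this library may therefore account for the enamel transcripts, while CALB1 (0.00322%) and SLC26A1 (0.196%) were near none. A biological difference between teeth was not tested.

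COL1A1 was higher in developing replicates 1 and 2 than in 3 and 4 (38.8% and 35.3% of the way to the functional mean). If functional-tooth tissue was present, other functional genes should stand part of the way too, and 24 genes chosen as low in replicates 3 and 4 stood at a median of 27.9% in replicate 1 and 44.3% in replicate 2. Genes chosen as low in replicates 1 and 2 stood at 3.34% in replicate 3 and 106% in replicate 4, the male library. The functional mean includes the male functional library. Of 10 other choices of low pair and library, 5 gave a median as high as in replicate 1, all in replicate 3 or 4. Replicates 1 and 2, with the other of them in the low pair, gave between -0.702% and 2.21%. The test thus decides nothing. Macrophage genes stood at -17% in replicate 1 (quartiles -32.7 and 3.73, with 19.4 needed) and at 6.29% in replicate 2 (quartiles -19.4 and 38, with 17.7 needed), which decides nothing for replicate 2. The low end of this scale includes developing replicate 4, whose macrophage list score (-0.02) lay above those of developing replicates 1 to 3 (-0.64, -0.59 and -0.6). Replicate 1 scored no higher than replicate 3, so no share of functional tissue with its macrophages was seen there. The quartiles are over genes in 1 library, so such a share is not excluded. Functional tissue or a later stage of these developing teeth may account for the pattern, and the labels do not give the stage.

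For the resorption list the interaction with the male pair had an adjusted p of 3.22e-09 with the preset correlation and 0.447 with an estimated correlation, but that pair is 1 functional and 1 developing library. Against the mean of the other 3 pairs, pair 1 stood at -1.01 ± 0.28 (SE over genes) and the male pair at 1.18 ± 0.27. Each of these means includes the other outlying pair. Functional minus developing, pairs 1 to 4 differed by -0.01, 0.67, 0.71 and 1.63. The excess of functional replicate 4 over functional replicates 1 to 3 was 0.88 ± 0.19 for the resorption list and 0.93 ± 0.19 for the macrophage list (a difference of 0.05 ± 0.27), while that of developing replicate 4 was -0.30 ± 0.14 and 0.59 ± 0.16. Over the male pair, less the mean of the others, the macrophage list had the smaller value (-0.84 ± 0.32 relative to the resorption list, adjusted p of its interaction 0.0807). The SE from the spread between the female pairs was 0.68. Macrophages minus resorption was 1.04, 0.22, -0.09 and -0.45 in pairs 1 to 4, so a share of macrophages stays open. Functional replicate 2 had a depth like that of functional replicate 4 and lay 0.97 below it (SE 0.20 over genes, and 0.34 from the spread between functional replicates 1 to 3). A like depth thus did not go with a like value, but this sets 1 library against 1 and does not exclude sequencing depth. Sex, number of teeth and a separate deposit of replicate 4 cannot be told apart (adjusted p = 0.4468 with an estimated correlation), since they change together.

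For V-ATPase subunits (adjusted p = 0.000221), matrix proteases (0.000221), dentin (0.000322), semaphorins (0.00576), respiration (1.01e-05) and endothelium (0.000855) camera with the preset correlation also gave a positive interaction with the male pair. The interaction was negative for enamel (0.000322), cell cycle (0.0015), red cells (0.0016) and oral mucosa (0.00082). With an estimated correlation these 10 adjusted p-values lay between 0.447 and 0.658.

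In functional replicate 4, CPM stood apart for CSTA (83.3), TNFAIP3 (10), CSF1 (16), GALNT15 (3.82), CIART (3.48) and PRUNE2 (0.521), the lymphocyte list score was 0.28, and COL1A1 with COL1A2 took 28.91% of counts. In developing replicate 4, CPM stood apart for CLDN5 (6.34), DDIT3 (4.35), IL22RA1 (54.6), TUBB3 (0.269), GALNT15 (0.346), SSTR2 (22) and EIF3G (102), and the macrophage list score was -0.02. In functional replicate 1, CPM stood apart for ELF3 (286) and IER3 (23), in functional replicate 3 for KIT (2.22), and in functional replicate 2 the Schwann cell score was -0.4. In developing replicate 1, CPM stood apart for GPNMB (12), CALCR (0.574), ESAM (26.4), KCNJ8 (2.66) and PERP (231). Names that match no gene symbol held 0.947% of counts in functional and 1.283% in developing teeth, with no control samples. GALNT15, CIART, PRUNE2, IL22RA1, TUBB3, SSTR2 and EIF3G had been chosen for a difference of replicate 4.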

How the results depend on the processing

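The collection covariate without functional replicate 1, voom with quality weights, the collection covariate for lists, libraries left out for the collection term and interaction, and the permutation of list scores were chosen after the data were seen. Genes higher and lower in functional teeth numbered 721 and 959 in DESeq2 (all 436 calls shared; adjusted p not given for 267 genes), 69 and 151 with the replicate block, 246 and 425 with the collection covariate (432 shared), 1 and 2 in females only, and 196 and 336 with the collection covariate without functional replicate 1. The other settings stayed within 1.5 times. With each library left out, the count of higher genes ran from 2 to 184 and of lower genes from 5 to 457. Lists past the threshold numbered 0 with an estimated correlation (smallest adjusted p 0.0898), 1 with fry, 0 in the exact permutation test (two-sided) and 13 to 17 with each library left out. In the permutation test 8 of 24 lists had the smallest p it allows, 0.0286, and an adjusted p of 0.0858. A list could pass only if many more lists had reached that p, so its count of 0 says little. The block changed no list call, and ended or added no call of a named gene other than 20 lost and 1 gained. For the male libraries DESeq2 called 965 higher and 765 lower, and with each library left out the counts ran from 1 to 615 and from 3 to 240; no block could be fitted, since collection follows from the replicate number. For the interaction DESeq2 called 20 genes and edgeR 0 with RLE, with the stricter filter and with each female library left out. Log2 fold changes that changed sign were TNFSF11 with the block (0.025), without functional replicate 1 and with the collection covariate (0.184), and from -0.305 to 0.297 with each library left out; OCSTAMP in females only (-0.307), in voom (-0.045), and from -0.286 to 0.774; HEMGN from -0.072 to 0.685. Of the lists, Schwann cells changed camera's direction without developing replicate 2 (mean -0.052; 0.846 at the highest, without developing replicate 4). The mean log2 fold change of a list changed sign in 17 comparisons, between -0.214 and -0.003: 7 for semaphorins, 5 for oral mucosa, 3 for Schwann cells, 1 for inflammatory mediators and 1 for granulocytes. None of these genes and lists passed the test with all libraries. Of 2446 comparisons of named genes with an alternative 1992 kept direction and side of the threshold, 356 lost the call, 89 gained it and 9 changed sign; of 384 for lists, judged by camera's or fry's direction, the numbers were 328, 46, 9 and 1. Apart from the estimated correlation, fry and the exact permutation test, calls were lost in matrix proteases, respiration and pericytes in females only, in muscle without the filter, and in pericytes, muscle, early response genes and Wnt genes with some libraries left out. Calls were gained in oral mucosa and red cells in females only and without developing replicate 4, in lymphocytes without functional replicate 4 or developing replicate 1, and in dental epithelium without functional replicate 1 or developing replicate 1. Of the 48 named genes past the threshold 48 lost the call in females only, where 25 of 50 simulated 4-fold changes were recovered, 48 lost it without functional replicate 4, and 1 without developing replicate 2. Without functional replicate 4, 37 of 50 simulated 4-fold changes were recovered, against 40 of 50 with all libraries, while the real counts fell to 2 and 6 genes, and the cause was not tested. At 8-fold the simulated numbers were 44 and 40. The 2 simulations were separate draws with independent genes and no male effect. They therefore do not show how much power the loss of this library costs in the real data.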

Other observations

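The genes here were chosen after their values were seen. The smallest adjusted p lay in HS3ST3B1, a heparan sulfate sulfotransferase gene, which fell from 65.1 ± 5.17 CPM in developing to 8.75 ± 2.09 CPM in functional teeth (mean ± SD, n = 4; log2 fold change -2.89 ± 0.18, edgeR adjusted p = 0.00238), and was lower in 4 of 4 functional libraries. Its adjusted p was 0.0318 with the replicate block and 0.0209 in females only. OLFML1, which encodes a secreted olfactomedin-like protein, fell from 48.1 ± 17.6 to 3.81 ± 0.535 CPM (log2 fold change -3.65 ± 0.28, adjusted p = 0.00664). The calcium channel subunit gene CACNA2D3 fell from 24.9 ± 9.21 to 1.71 ± 0.508 CPM (log2 fold change -3.85 ± 0.35, adjusted p = 0.00947, and 0.038 in females only). HHIP, a hedgehog antagonist gene induced by the pathway, averaged 61.8 ± 58.1 CPM in developing and 4.36 ± 3.84 CPM in functional teeth and did not pass (-3.84 ± 0.92, adjusted p = 0.0645).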
